A study of Mus musculus with 4 samples.

How the data were processed

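RNA was sequenced from T cells of mice of the strain C57BL/6NJ, described in the labels as primary cells. The labels give 1 group of 4 biological replicates and no second condition, so no comparison between groups was made. The labels call the assay total RNA sequencing, while the name of the linked library protocol says polyadenylated RNA, and the linked culture protocol is named for differentiation of CD4 T cells. All 4 libraries carry the same donor entry, and sex was not recorded. Nothing else in the labels says whether the replicates came from separate animals or cultures, so every spread given here is the spread between these 4 libraries.

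The deposited values are raw counts of read pairs per gene. They were made with featureCounts 1.4.6-p4, per the file headers, on the exons of GENCODE release M13 for the mouse assembly mm10. Pairs were counted as fragments with both ends mapped and with the reverse strand setting, per the file headers, and neither the option for multiply mapped reads nor that for reads overlapping several genes was switched on. Genes with near-identical copies, and genes that overlap on the same strand, can therefore lose counts, and their levels are uncertain. Input alignments were named as STAR output, per the file headers, and the version of the aligner is not given in the sources used here. The same headers name the alignments as Th0, activated, sorted and 72 h, and their replicate numbers match the labels. Of the 50600 genes in the files, 50376 (99.6%) were matched by identifier to GENCODE M21, from which symbols and gene classes were taken. Coordinates are those of the deposited files on mm10.

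Counts summed to 34978213 in replicate 1, 118937382 in replicate 2, 42274502 in replicate 3 and 95356041 in replicate 4. A gene with a count of 0 could have had up to 3 counts at 95% confidence, which is 0.0858, 0.0252, 0.0710 and 0.0315 CPM (counts scaled to the library total) in replicates 1 to 4. Such limits, and the Wilson 95% intervals given for shares, cover counting error only, since reads without molecular identifiers are not independent molecules.

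Length-normalized transcript abundances (TPM) were computed here from the deposited counts and the exonic length of each gene. The design fixed before the data were examined had assumed expected counts and TPM from RSEM. The whole counts in the files replaced the rounded expected counts in every test, and alternatives that needed a posterior mean TPM were not run. Genes were compared inside each library as differences of log2(TPM + 0.1), which understate differences of low genes, and gene lists as differences of their medians on that scale. Each contrast was tested over the 4 libraries with an exact two-sided sign-flip permutation test. The smallest p this test can give with 4 libraries is 0.125, so no contrast can pass 0.05. Benjamini-Hochberg adjustment ran over the 25 gene contrasts and, separately, over the 20 list contrasts.

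Genes more variable between libraries than usual at their level were sought with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr, libraries were scaled with TMM, dispersions were estimated with an intercept only, and the goodness of fit of each gene under the trended dispersion was tested with Benjamini-Hochberg adjustment at 0.05. With a single group this filter needs the minimum count in all 4 libraries, so genes absent from some libraries, such as those on the Y chromosome, were not tested. Log2 CPM used a prior count of 2. On simulated counts for 14269 genes, 200 genes raised 4-fold in 1 library were called in 90.0% of cases, those raised 2-fold in 72.0% and those raised 1.5-fold in 40.0%, and data with no changed gene gave 0 calls. Every simulated gene had the trended dispersion, so calls that come from ordinary scatter of genes around the trend were not covered.

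Gene lists were tested for a joint shift between libraries by the range over libraries of the median centred log2 CPM, against 10000 random lists of the same size matched on expression in 20 bins. Lists with 5 or more tested members entered, and adjustment ran over the 26 lists. On simulated data, 30 random lists were used, and 15 of them were raised by 0.3 log2 in 1 library. All 15 were recovered, with 0 false calls among the lists left unmoved. The values of each gene were permuted independently over the libraries, so false calls from genes that vary together were not covered. The planted shift was also larger than the range of some lists called below, such as 0.19 log2 for glycolysis. Pairs of libraries were compared for duplication with a chi-square test of counts. The statistic per degree of freedom lay between 26.7 and 76.1, so no pair agreed within sampling noise and all 4 libraries were counted.

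Named genes were chosen by a rule fixed before the data were examined. It took the 10 nuclear protein-coding genes with the highest mean TPM, the 4 most abundant members of each of 37 gene lists and all genes of the gene contrasts. It also took, of the variable genes with a mean TPM of 5 or more, the 25 with the largest SD, leaving out receptor and immunoglobulin segments and provisional symbols, and up to 4 variable members of each list. The 37 lists hold 481 distinct genes, 16 of them in more than 1 list. Where another gene is named, the text says so. Some genes that the rule and the contrasts cover are not reported here, though their contrasts stay in the families over which p was adjusted. Alternatives covered the TPM minimum, the pseudocount, CPM in place of TPM, other filters, DESeq2 1.42.0 size factors and dispersion outliers, a common dispersion, a limma 3.58.1 variance test and leaving out each replicate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.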

Results

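Gene expression was measured by RNA sequencing in 4 libraries of mouse T cells, biological replicates 1 to 4 of 1 group. Total counts were 34978213, 118937382, 42274502 and 95356041. Levels are given as TPM, mean ± SD over n = 4 libraries, and no contrast can reach a p below 0.125 with 4 libraries. In all 4 libraries, 12535 genes reached a TPM of 1 or more, of which 10868 were protein-coding. The most abundant nuclear protein-coding genes were Rplp1, a ribosomal stalk protein, at 10011 ± 548 (SD, n = 4) and Actb, cytoplasmic actin, at 7242 ± 189 (SD, n = 4), followed by Rpl8, Rplp0, Eef1a1, Eef2, Rps2, Hsp90ab1, Rpl4 and Rps15.

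The first question was which cells the libraries held. All 20 members of the T cell identity list reached a TPM of 1 or more in every library. Trac, the constant region of the T cell receptor alpha chain, stood at 1892 ± 92.1 (SD, n = 4), Trbc2 at 1567 ± 49.6 and the surface receptor Cd5 at 1538 ± 89.2. Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221, minus strand, mm10) stood at 975.7 ± 29.3 (SD, n = 4) and Cd8a at 0.267 ± 0.185, a difference of 11.52 ± 0.82 on the log2 scale that had the same direction in 4 of 4 libraries (exact sign-flip p = 0.125, adjusted p = 0.142) and was 9.60 with a pseudocount of 1. Cd8b1, the partner chain of Cd8a, stood at 21.4 ± 5.49. Zbtb7b, the regulator of the CD4 lineage, exceeded Runx3, that of the CD8 lineage, by 0.54 ± 0.03 log2 in 4 of 4 libraries (exact sign-flip p = 0.125). Trac exceeded Trdc, the delta chain constant region, by 11.17 ± 0.14 log2 in 4 of 4 libraries (exact sign-flip p = 0.125), or by 9.15 with CPM.

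Lists of other cell types lay far below the T cell list. The median of the T cell identity list exceeded that of the gamma-delta T, NKT and NK list by 10.52 ± 0.67 log2, of the B cell list by 9.55 ± 0.33, of the dendritic and antigen presenting list by 10.03 ± 0.34, of the macrophage and monocyte list by 11.91 ± 0.26 and of the stromal, endothelial and epithelial list by 12.01 ± 0.14 (SD, n = 4). For the neutrophil, mast cell and basophil, erythroid and platelet lists, the median TPM was 0 in every library, and each difference was 12.21 ± 0.07. That value is set by the T cell list and the pseudocount of 0.1, and its SD is the spread of the T cell list alone. All 9 contrasts had the same direction in 4 of 4 libraries (exact sign-flip p = 0.125, adjusted p = 0.132). With a pseudocount of 1 the differences were 8.21 to 8.89, and with only members at a TPM of 1 or more in at least 1 library that of the dendritic and antigen presenting list was 3.62 and those of the other lists with such members 7.14 to 8.45. S100a8, a neutrophil calcium-binding protein, and Lyz2, a macrophage lysozyme named after its values were seen, had 0 counts in all 4 libraries, which allows at most 0.0252 CPM in the deepest library. Single members stood above their lists. Ighm, the constant region of the IgM heavy chain, was at 454.4 ± 42.1, while Igkc was at 1.61 ± 0.499 and Cd79b at 2.06 ± 0.717. Cd74, the invariant chain of antigen presentation, was at 454.9 ± 43.7, H2-Eb1 at 62.5 ± 6.13 and H2-Ab1 at 38.3 ± 3.50. Pecam1, an adhesion receptor also found on leukocytes, was at 20.5 ± 1.55, and Cd68 at 13.5 ± 1.69.

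**Figure D1:**
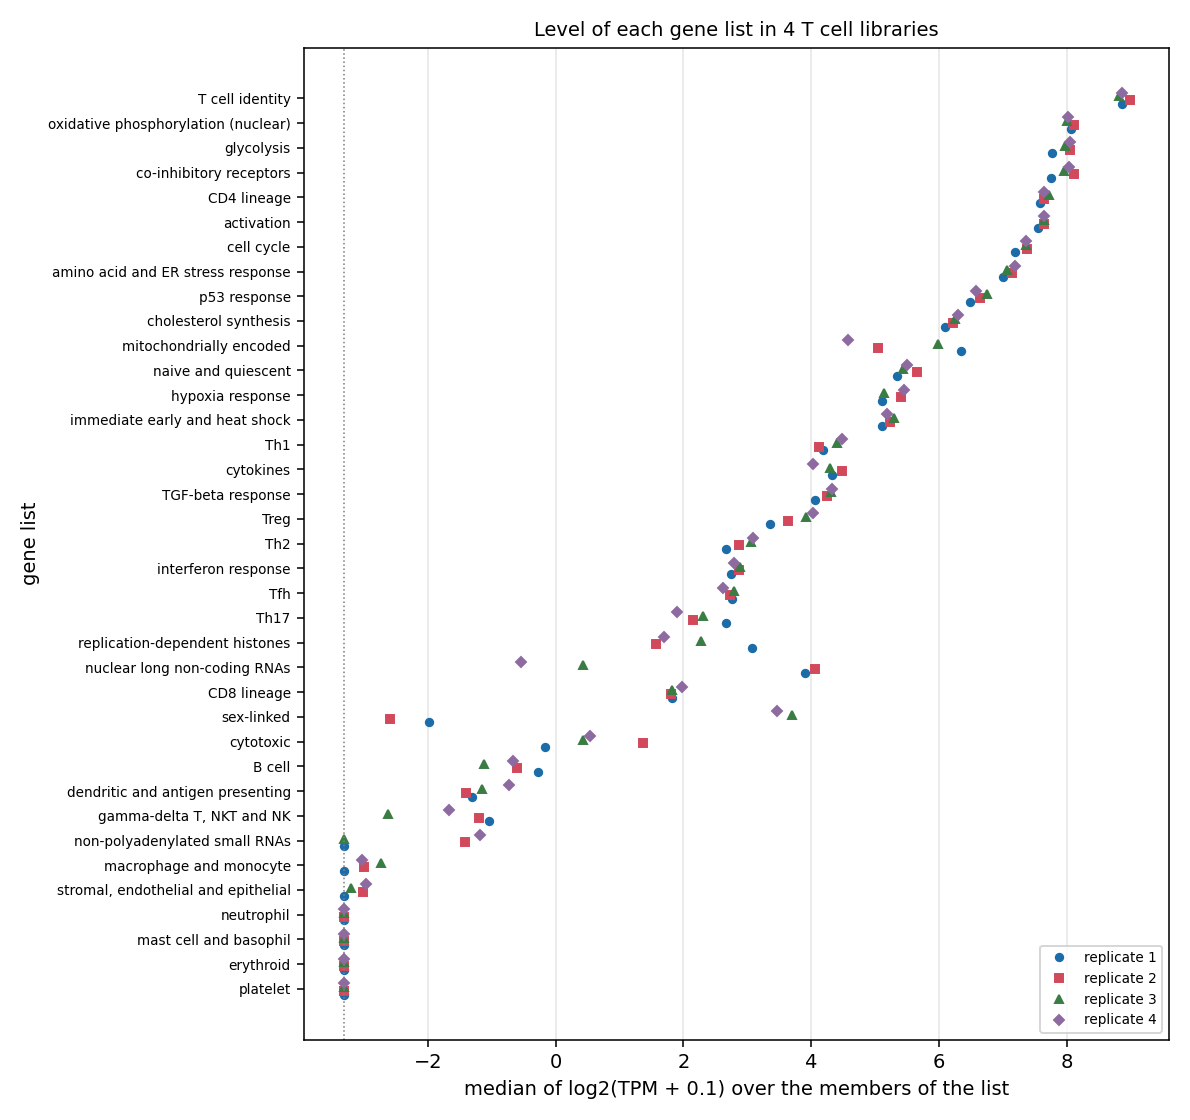
Median of log2(TPM + 0.1) over the members of each gene list, 1 point for each of the 4 libraries. The dotted line marks a TPM of 0, where the neutrophil, mast cell and basophil, erythroid and platelet lists lie, and the T cell identity list lies highest, at 8.82 to 8.99.

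Genes of activation and division were abundant. All 21 members of the activation list reached a TPM of 1 in every library, led by the costimulatory receptors Tnfrsf4 at 2642 ± 96.1 (SD, n = 4) and Tnfrsf18 at 1201 ± 77.5, by Nr4a1, a gene induced by receptor signalling, at 663.3 ± 39.8, and by the transcription factor Irf4 at 527.7 ± 27.8. The list's median exceeded that of the naive and quiescent list by 2.15 ± 0.10 log2 in 4 of 4 libraries (exact sign-flip p = 0.125), or by 1.47 with CPM. Within the latter list the homing receptor Ccr7 stood at 1262 ± 137, Dapl1 at 472.8 ± 59.6, and the transcription factors Tcf7 at 310.8 ± 9.89 and Bach2 at 108.1 ± 6.97. The activation marker Cd44 stood at 184.4 ± 9.29. Of 10 co-inhibitory receptors, 8 reached a TPM of 1 in every library, led by Ctla4 at 858.8 ± 22.0, Pdcd1 at 523.3 ± 26.4, Cd200 at 490.6 ± 25.6 and Btla at 372.8 ± 21.0. All 30 cell cycle genes did so, with the replication genes Mcm3 at 441.4 ± 22.2, Pcna at 439.5 ± 17.4, Rrm2 at 429.3 ± 8.59 and Mcm5 at 398.0 ± 20.7.

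Metabolic and stress lists were also expressed throughout. All 17 glycolysis genes reached a TPM of 1 in every library, with Ldha, lactate dehydrogenase, at 3706 ± 283 (SD, n = 4), Gapdh at 1896 ± 138, Pkm at 1806 ± 172 and Tpi1 at 1777 ± 159. The same held for all 21 nuclear genes of oxidative phosphorylation, led by Atp5b at 1650 ± 61.9 and Atp5a1 at 1385 ± 12.03, all 21 of cholesterol synthesis, led by Srebf2 at 450.0 ± 33.8, and all 16 of the hypoxia response, led by Bhlhe40 at 752.9 ± 41.4. It also held for all 17 of the amino acid and ER stress response, led by Atf4 at 657.0 ± 28.5, all 15 immediate early and heat shock genes, led by Hspa8 at 1420 ± 65.0, and all 13 of the p53 response, led by Cdkn1a, an inhibitor of cyclin-dependent kinases, at 885.1 ± 41.0. Of 21 interferon response genes, 15 reached it, led by Bst2 at 387.6 ± 37.9. Of 12 TGF-beta response genes, 11 did, led by Ctla4, which is also in the list of co-inhibitory receptors. Ski came next, at 67.4 ± 2.60.

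Next, 4 regulators of T helper subsets were compared inside each library. Gata3, the Th2 regulator (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034, minus strand, mm10), was at 39.7 ± 4.23 (SD, n = 4), Bcl6, that of follicular helper cells, at 6.52 ± 0.346, Tbx21, that of Th1 cells, at 3.36 ± 0.416, and Foxp3, that of regulatory T cells, at 1.94 ± 0.454. All 6 pairs of these 4 kept one direction in 4 of 4 libraries (exact sign-flip p = 0.125 each, adjusted p = 0.142). With CPM in place of TPM, the log2 difference of Tbx21 minus Foxp3 was 0.13 in place of 0.78 and had no common direction (exact sign-flip p = 0.50). The most abundant member of the Th17 list was Ccr6, a chemokine receptor, at 438.3 ± 34.7. Those of the Th1 list were the chemokines Ccl4 at 688.6 ± 118 and Ccl3 at 430.6 ± 73.9, of the Th2 list Stat6 at 280.8 ± 18.3, of the regulatory list Capg at 533.6 ± 26.9 and of the follicular list Cd40lg at 402.2 ± 11.3. The Th1 median exceeded the Th17 median by 2.05 ± 0.44 log2 in 4 of 4 libraries. That direction was lost when only members at a TPM of 1 or more in at least 1 library were kept, where the difference was -0.0077.

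Among cytokines, Il2, the T cell growth factor, was at 620.8 ± 80.0 (SD, n = 4), and Il2 exceeded each of the other 4 compared cytokines in 4 of 4 libraries (exact sign-flip p = 0.125 each). Il17a stood at 5.66 ± 2.67 and exceeded Il4, at 0.857 ± 0.562, since the log2 difference of Il4 minus Il17a was -2.66 ± 0.35 in 4 of 4 libraries (-1.81 with a pseudocount of 1). Ifng stood at 0.413 ± 0.490, from 0, 4, 18 and 19 counts in replicates 1 to 4, and Il10 at 0.0611 ± 0.0789. Ifng did not differ from Il4 in one direction, being lower in 2 libraries and higher in 2 (exact sign-flip p = 0.50). Of the 23 cytokines, 15 reached a TPM of 1 in every library, led by Tnfsf11 at 731.8 ± 23.7, and including Tnfsf8 at 396.1 ± 18.4 and Lta at 374.6 ± 29.9. Of the 11 cytotoxic genes, 5 did, led by the proteoglycan Srgn at 316.3 ± 17.3, while Gzmb was at 21.2 ± 4.23.

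**Figure D2:**
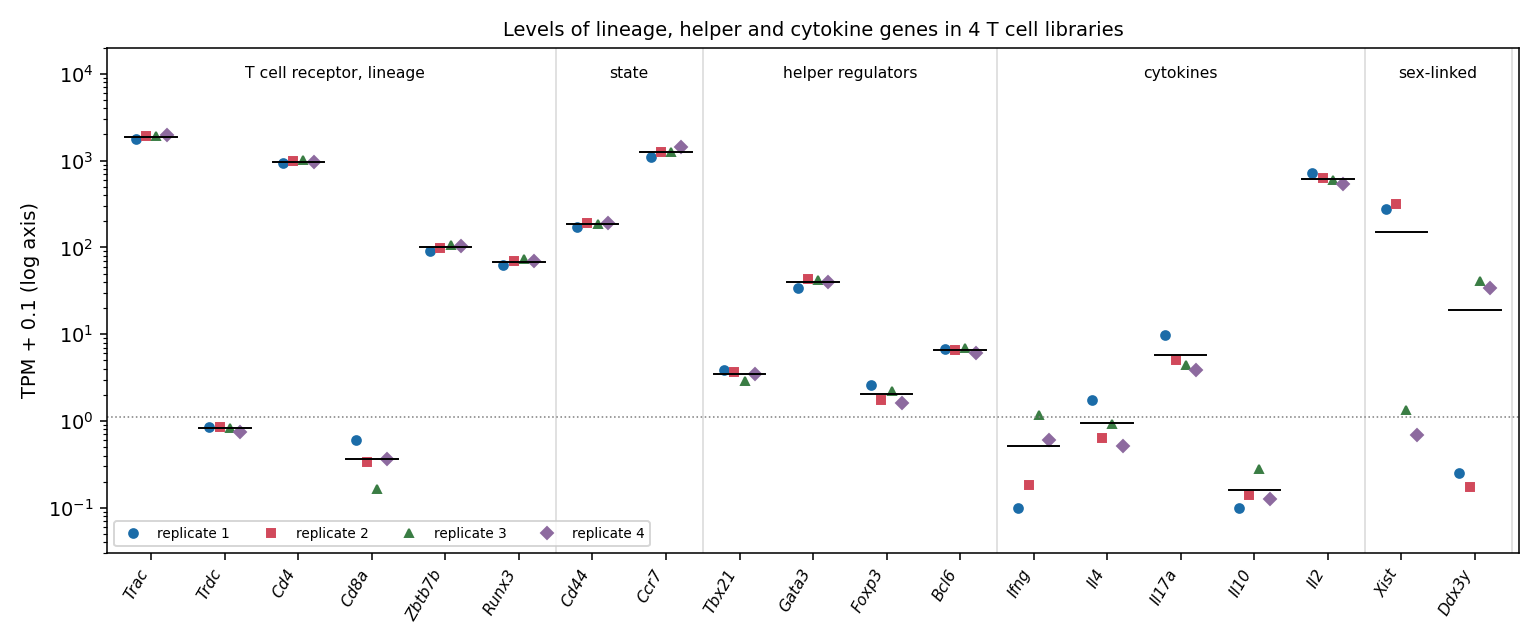
TPM + 0.1 on a log axis for lineage, state, helper regulator, cytokine and sex-linked genes, 1 point for each of the 4 libraries, with bars at the mean and a dotted line at a TPM of 1. Cd4 lies near 976 and Cd8a below 1 in every library, Gata3 lies above the other 3 helper regulators shown, and Xist and Ddx3y are each high in 2 libraries only.

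Receptor segments were spread over many genes. Of 35 Trbv segments, 22 had 10 or more counts in all libraries, as did 54 of 128 Trav segments. The most used Trbv segment took 12.7% of Trbv counts in replicate 1 (Wilson 95% interval 11.99% to 13.4%), 13.4% in replicate 2 (13.04% to 13.8%), 14.6% in replicate 3 (13.9% to 15.3%) and 12.6% in replicate 4 (12.1% to 12.99%). It was Trbv13-2 in replicates 1 to 3 and Trbv31 in replicate 4. The most used Trav segment took 5.45% to 6.80%. Segments share sequence, so the share of any single one is uncertain.

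Across RNA classes, mitochondrially encoded genes took 1.12% ± 0.0985 of counts (SD, n = 4) and ribosomal protein genes 4.90% ± 0.315. The 10 genes with most counts took 4.24% ± 0.370, the replication-dependent histones 0.00291% ± 0.00077 and small RNAs without a poly(A) tail 0.00122% ± 0.00092, or 0.000797% without replicate 1. Of the 13 mitochondrially encoded genes, mt-Co1 stood at 10297 ± 1232, while mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, named after their values were seen, were below a TPM of 1 in every library. Their levels are therefore uncertain under counting of singly mapped reads, and the share of the class can be too low.

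The 4 libraries were then compared with each other. Across 24114 genes, Pearson's r of log2(TPM + 0.1) lay between 0.958 and 0.973 for the 6 pairs and Spearman's rho between 0.932 and 0.949. Genes are not independent replicates, so these values only describe agreement. The common biological coefficient of variation was 11.5%, and the median SD of log2 CPM was 0.12. The first principal component held 45.4% of the variance. Of 14269 genes tested with edgeR's goodness of fit under the trended dispersion, 66 varied more than the trend (Benjamini-Hochberg adjusted p below 0.05), and 812 had an unadjusted p below 0.05. The count depended on the test, with 955 calls under a common dispersion and 27 under limma's variance test, and was 41 without replicate 1.

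The sex-linked and X-linked genes were among the most variable. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217, minus strand, mm10), had 278.4 and 315.9 TPM in replicates 1 and 2 and 1.25 and 0.586 in replicates 3 and 4 (SD 4.91 log2, edgeR adjusted p = 0 to machine precision). The Y-linked helicase Ddx3y, not tested because it was near 0 in 2 libraries, ran the other way, and the Xist minus Ddx3y difference had no common direction (exact sign-flip p = 0.625). The X-linked genes Kdm6a, a histone demethylase, Eif2s3x, a translation factor, and Pbdc1 also varied, Kdm6a with 32.3, 34.1, 20.4 and 17.2 TPM in replicates 1 to 4 (edgeR adjusted p = 4.91e-15). Mid1, on chromosome X, had 10.6, 20.8, 7.75 and 1.54 TPM (adjusted p = 1.67e-63).

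Other called genes were high in replicates 1 and 3, the 2 libraries with fewest counts. Malat1, a nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672, minus strand, mm10), had 348.0, 63.2, 246.0 and 59.3 TPM in replicates 1 to 4 (edgeR adjusted p = 5.25e-77). The small nuclear RNA Rn7sk had 149.6, 21.0, 80.6 and 15.1 TPM (adjusted p = 1.92e-27), and the linker histone Hist1h1e had 22.9, 2.86, 14.1 and 1.13 (adjusted p = 1.88e-12). Mir6236, Lars2, mt-Nd6, Hist1h3e and, at a mean of 0.476 TPM, Kcnq1ot1 also had their 2 highest values there. Neat1, another nuclear RNA, had 14.9, 16.6, 21.9 and 16.6 TPM, and Rpph1, the RNA of ribonuclease P, had 66.1, 37.8, 32.2 and 21.2. These 2 were not higher in both, and edgeR called them only when adjusted over the list alone (adjusted p = 0.0173 and 0.00845). Of the 66 called genes, 30 were higher in both of these libraries than in both others, 7 were lower in both, and 29 did neither. Alpl, alkaline phosphatase (chromosome 4, 137741733 to 137796384, minus strand, mm10), was lower in both, with 3.25, 11.3, 3.25 and 14.8 TPM (adjusted p = 8.68e-20), as were Bin2 with 138.8, 264.9, 161.2 and 258.0, Ece1 and Ubxn11.

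**Figure D3:**
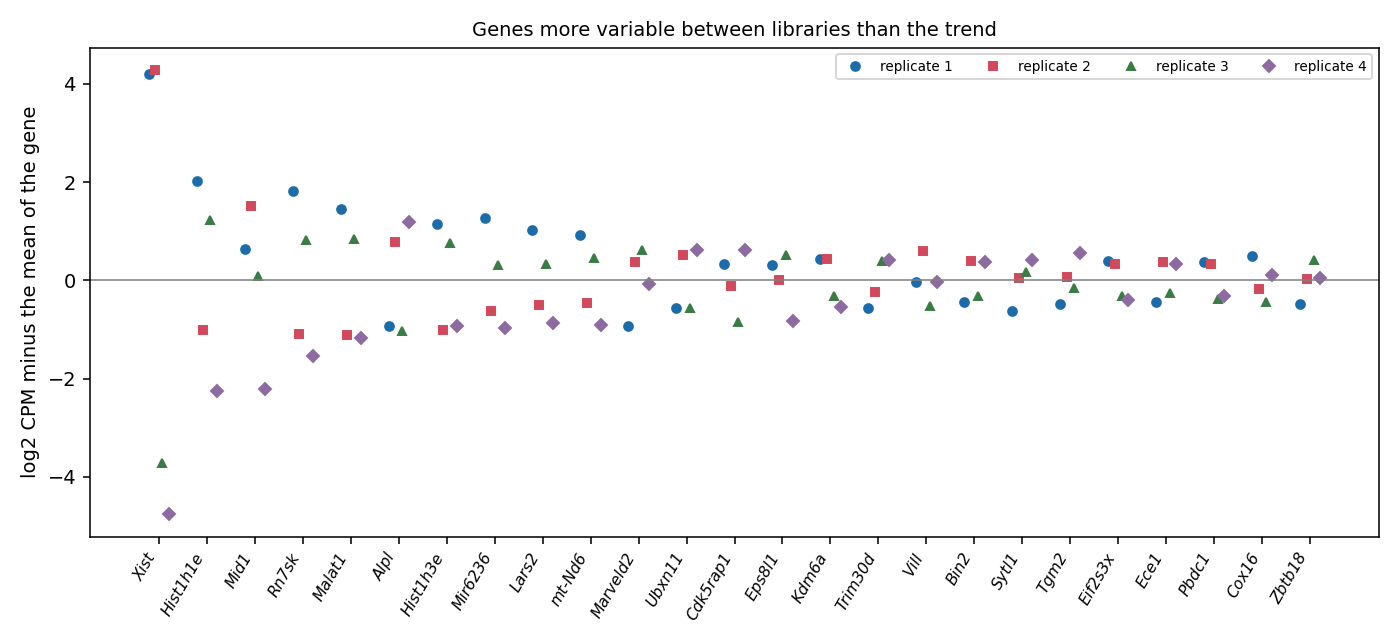
Log2 CPM minus the mean of each gene, 1 point for each of the 4 libraries, for the 25 named variable genes ordered by SD. Xist spans the widest range, with replicates 1 and 2 above 4 and replicates 3 and 4 below -3, and Malat1 and Rn7sk lie above 0 in replicates 1 and 3.

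Of the 375 tested list genes, 10 were called over all genes tested, and 16 were called adjusted over the list alone. Those 10 included the chemokines Ccl4 (1.52-fold from the lowest to the highest library, edgeR adjusted p = 4.06e-04) and Ccl3 (1.60-fold, adjusted p = 5.08e-04), the interferon-induced protease Usp18 (3.72-fold, adjusted p = 0.0456) and the histone Hist1h1d (9.21-fold, adjusted p = 0.00188). Among lists, each taken by its tested members, 7 of 26 shifted between libraries more than matched random lists. The interferon response list lay at -0.18, -0.07, 0.06 and 0.16 log2 in replicates 1 to 4 (permutation adjusted p = 0.00173), parting replicates 1 and 2 from 3 and 4 as Xist and Ddx3y did. Of the mitochondrially encoded list, only 7 of 13 members were tested, and they lay at -0.12, 0.01, 0.18 and -0.08 (permutation adjusted p = 0.00173). The median level of all 13, with 6 below a TPM of 1, was 6.34, 5.04, 5.98 and 4.57 log2, which orders the libraries otherwise. Nuclear oxidative phosphorylation lay at 0.08, -0.01, -0.10 and 0.02 (permutation adjusted p = 0.00173) and glycolysis at -0.10, 0.08, -0.07 and 0.08 (adjusted p = 0.00195). The glycolysis list was thus lower in both libraries with fewest counts, the same 2 in which Malat1 and Rn7sk were highest. The Th17, immediate early and heat shock, and amino acid and ER stress lists also passed, with adjusted p of 0.0473, 0.0483 and 0.0483. After a correction for GC content and length, which left 4 lists, their adjusted p was 0.0812, 0.0689 and 0.0689, while their range over the libraries went from 0.23, 0.17 and 0.14 log2 to 0.18, 0.15 and 0.14. Before it, over 9212 protein-coding genes, Spearman's rho of centred log2 CPM with GC content was -0.34, 0.0037, 0.085 and 0.38 in replicates 1 to 4. With length it was -0.22, 0.016, 0.43 and -0.23. With means in place of medians 3 lists passed, of which the interferon response and oxidative phosphorylation lists were 2 of the 7 and the histone list was not, so glycolysis and the mitochondrially encoded list were lost. Without replicate 4, 4 of the 7 passed, and without replicate 3, 5 lists passed, of which 3 were among the 7.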

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

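In each set of 4 libraries, a value was picked out where 1 library lay far from the others relative to the whole range. Of 237 reported values 16 met this, against 11.85 that chance alone gives at 1 in 20. No explanation was tested for them.

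In replicate 1, 7 levels were picked out, of which 6 were low and 1 high. Trac was 1755 TPM against 1926 to 1949 in the others, Irf4 486.2 against 538.0 to 545.4, Stat6 253.6 against 287.6 to 293.0, Il4ra 122.6 against 148.1 to 150.8, Srebf2 399.5 against 462.0 to 470.2 and Gbp2 55.6 against 65.8 to 66.4. None of these 6 was called variable by edgeR. As CPM scaled with TMM, their highest library was 1.06 (Trac) to 1.16 (Il4ra) times their lowest. Hist1h1d was 9.88 TPM against 1.03 to 2.49. Also in replicate 1, the log2 difference of Il17a minus Il2 was -6.22 against -7.09 to -6.97, and the median of the Th1 list minus that of the Treg list was 0.84 against 0.46 to 0.50.

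In replicate 3, Rpl4 was 4129 TPM against 4365 to 4411, Hspa5 524.3 against 562.8 to 569.5, and Gp1ba 0.0851 against 0 in the others. The log2 difference of Tbx21 minus Bcl6 was -1.27 there against -0.84 to -0.82. In replicate 4, Sox13 was 1.37 TPM against 0.662 to 0.740 and Trdc 0.648 against 0.738 to 0.756. In replicate 2, Epcam was 3.47 against 3.17 to 3.21.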

How the results depend on the processing

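Contrasts were compared by direction, counts by whether they stayed within 1.5 times, and shares and r by whether they stayed within 1 SD over the libraries or their pairs. Of 354 recomputed values, 326 met this, 17 moved, 10 reversed and 1 lost its call. No contrast could pass 0.05 under any setting, so only directions were compared there, and 149 of 150 gene contrast values kept that of their mean. The exception was Xist minus Ddx3y, which ranged over leaving out single replicates from -0.16 (without replicate 2) to 5.33; the 2 genes are each high in different libraries. Of the 137 list contrast values, 9 reversed, all between helper lists. With members at a TPM of 1 or more only, Th1 minus Th2 became -0.23, Th1 minus Th17 -0.0077, Th1 minus Treg -0.38, Th1 minus Tfh -0.82, Th2 minus Tfh -0.58 and Treg minus Tfh -0.44, since low members then no longer pull the medians down. With CPM, which are not divided by length, Th1 minus Treg became -1.42, Th1 minus Tfh -0.54 and Th2 minus Tfh -2.05.
The 66 variable genes became 955 under a common dispersion, 27 under limma's variance test, and 41 to 68 when single replicates were left out. Added after seeing the data, a filter needing 2 libraries gave 128, of which 52 were shared, because it admits genes absent from some libraries. The 7 shifted lists became 3 with means (2 of them shared), 4 after the added correction for GC content and length, and 4 to 9 without single replicates. The lowest Pearson r, 0.958, became 0.938 for genes at a mean TPM of 1 or more and 0.985 with a pseudocount of 1, and was 0.958 to 0.965 without single replicates. The 76 receptor segments became 48 at a minimum of 30 counts. As percent of TPM, the classes took 2.73% (mitochondrially encoded), 10.4% (ribosomal protein), 0.0124% (histones), 0.0119% (small RNAs) and 5.71% (10 most abundant genes), since short genes gain weight. Apart from these stated constructions, the cause was not tested. Alternatives based on a posterior mean TPM were not run. Depth limits the low genes most, and Ifng and Il10 lie near the limit of a count of 0.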

Other observations

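All tests in this part, apart from the shift test of the histone list, were chosen after the results they bear on had been seen. The genes Slc15a2, Oas3, Rnf213, Gpat2, Gm42418, Mid1-ps1, Pqlc2, Emc1, Iffo2, Csrnp2, Tuba1b, Kdm5c and Ddx3x were named after their values were seen.

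The called genes Oas3, Rnf213 and Trim30d, not tested as a group, were lowest in replicate 1. Oas3 had 13.1, 18.5, 22.3 and 23.7 TPM in replicates 1 to 4, Rnf213 15.6, 21.6, 24.2 and 22.1, and Trim30d 8.51, 11.4, 17.7 and 17.8. Slc15a2, Gpat2 and Mid1-ps1 were called only with the added filter needing 2 libraries. The peptide transporter Slc15a2 had 0, 17, 354 and 521 counts, lower in replicates 1 and 2 than in 3 and 4 as the Y-linked genes were, and Gpat2 had 4, 99, 0 and 130. Mid1-ps1, annotated on the Y chromosome as a pseudogene of Mid1, had 24.9, 46.7, 14.3 and 0.0543 TPM, in the same order as Mid1, and reads shared between both copies make these 2 levels uncertain.

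The first pattern was the parting of libraries by sex-linked genes. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 0.772, 0.361, 220.7 and 197.2 CPM in replicates 1 to 4, and Xist had 278.4, 315.9, 1.25 and 0.586 TPM. In no library did both reach 1% of their highest library, the largest lower value being 0.396%, which argues against a mixture of cells of both sexes in any library. The Y share of counts over these genes and their X copies differed 616-fold between libraries, which argues against shared reads, and the summed Y level differed 610.5-fold, which argues against 1 animal as the source of all 4 libraries although they carry 1 donor entry. Kdm5c stood at 162.1, 174.0, 124.9 and 117.5 TPM and Ddx3x at 304.6, 326.8, 290.8 and 271.8. The labels record no sex. Replicates 1 and 2 had high Xist with very low Y-linked genes, and replicates 3 and 4 the reverse. The X copies Kdm5c, Ddx3x, Kdm6a and Eif2s3x were also each higher in replicates 1 and 2. These values argue against male cells in replicates 1 and 2 and against female cells in replicates 3 and 4. No other biological explanation was tested, and any replicate difference that follows this parting stays confounded with it.

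The second pattern was the higher level of some RNAs without a poly(A) tail, such as Rn7sk, in replicates 1 and 3, the libraries with fewest counts. Gm42418, in neither the histone nor the small RNA list, was also higher there, with 17330, 1881, 9478 and 1083 TPM. The pattern did not cover every member of these lists, since Rpph1 and Hist1h2ae were not higher in both. The histone list did not pass the shift test with medians (permutation adjusted p = 0.181) but did with means. Of 30 called genes higher in both, 29 (96.7%) stayed so after thinning to equal depth. Thinning keeps the expected share of each gene, so this was largely fixed beforehand and decides nothing about depth. The cell cycle list differed by a median of -0.043 ± 0.047 log2 (SD over 30 genes), against 0.27 for 13 histones. That list holds genes of replication and of mitosis together, so its median cannot decide whether more cells were in S phase. Its replication genes named above were not higher in both libraries. In replicates 1 to 4, Mcm3 had 413.5, 462.2, 433.8 and 456.1 TPM and Mcm5 372.0, 406.9, 392.6 and 420.4. Pcna had 455.8, 436.4, 416.5 and 449.4 TPM and Rrm2 432.7, 439.2, 419.4 and 425.7. For these genes, the values argue against more cells in S phase. Of 15 tested members of the histone and small RNA lists, 6 (40.0%) were higher in both, against 15.5% of other tested genes and 16.7% by chance order (1-sided Fisher's exact p = 0.0198, over genes, which are not independent). Without the called members that prompted the pattern it was 3 of 12 (exact p = 0.282). Only 2 of the 14 small RNAs were among those tested. Of the untested ones, Scarna2 was higher in both, with 14.3, 1.72, 7.45 and 0.818 TPM in replicates 1 to 4, and Vaultrc5 was not. A larger carry-over of such RNA therefore stays open, as do other library steps that go with depth. No other biological explanation was tested.

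The third pattern was that some genes parting replicates 1 and 3 from 2 and 4 lay close together: of 8935 autosomal protein-coding genes, 31 parted these libraries by more than 0.25 log2 in either direction, and 14 pairs of them lay within 2 Mb. Only 10 of the 31 were in any pair, and Alpl, Ece1, Pqlc2, Emc1 and Iffo2 on chromosome 4 made 10 of the 14 pairs, while Tuba1b, Csrnp2 and Bin2 on chromosome 15 made 3. After correction for GC content and length 17 pairs were found, which argues against those trends as the cause. Shifting the labels along the gene order, the first test run, gave p = 0.0857 by permutation but keeps neighbours together, and assigning them to genes at random, chosen after that p was seen, gave p = 0.0002 (adjusted over the 3 pairings of libraries, 6.00e-04), 0.0267 for the 4 pairs left without chromosome 4 (0.131 by shifting), 0.0329 for replicates 1 and 2 against 3 and 4, and 0.373 for 1 and 4 against 2 and 3. A chromosome segment that differs between animals cannot be told apart from a likeness of neighbouring genes, because the 2 tests disagree, 1 of the other pairings also passed and the labels give no genotype.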
